A study of Mus musculus with 6 samples.

How the data were processed

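RNA was measured in 3 libraries and H3K9me3 in 2 CUT&RUN samples of the hybrid trophoblast stem cell line C/B 6.2, with an IgG sample as the control. RNA libraries were made with a stranded total RNA kit for low input, per the labels' protocols. The submitters' processing notes name FastQC, Trimmomatic, UMI-tools, STAR, HTSeq 0.9.1, SAMtools 1.11 and MACS2, and the builds GRCm38, mm10 and mm39, without saying which served which file. The names of the peaks in the deposited lists also carry the words Bowtie2 and SNPsplit. How RNA reads were assigned to an allele, and whether they were counted by strand, is not given in the sources used here.

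For each RNA library the authors deposited 2 files of raw read counts per gene, one for the C57 and one for the CAST allele. Each holds 55487 Ensembl genes with symbols and no rows of unassigned reads. The files do not say whether UMIs were collapsed, so the intervals and zero limits given here cover counting error only. Totals of both alleles were 1981167, 1044264 and 1552265 counts per library. Of the tested genes 99.4% were placed on a chromosome by symbol with the RefSeq table of GRCm38.p6, which served only for chromosomes, neighbours and windows.

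For each H3K9me3 sample the authors deposited 1 list of broad peaks per allele, called per sample with MACS2 and not on pooled samples. The score in these deposited lists is 10 times the −log10 q value, rounded down, as far as the shared lists allow the test. The lists hold autosomes only and are in mm39 for sample 1 by its name. The sample 2 lists name no build and overlap sample 1 at the same coordinates. The 2 lists deposited under the IgG sample hold no IgG data. On the autosomes they held exactly the sample 1 peaks of an allele that overlap a sample 2 peak of that allele, and with the X, which could not be tested, they held 5317 C57 and 5126 CAST peaks. Those deposited lists also give the authors' fold enrichment ratio and the −log10 p and q value of each peak, used here only to describe or filter peaks. Their coordinates differ from the per-sample lists and are taken as GRCm38, which is inferred from the values. The per-sample lists could not be set against genes, since no mm39 annotation was used here. There was no IgG background to set beside the peaks.

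Allelic counts were tested with edgeR 4.0.16 (quasi-likelihood, R 4.3.3), with the library as a block, TMM scaling over the 6 allele columns, and genes averaging at least 10 counts of both alleles per library. The block comes from the construction of the files, since both allele columns come from 1 library. Residual counts of the same library correlated at 0.105, 0.229 and 0.257, and those of different libraries were all negative. Residuals were taken from each allele's mean over the 3 libraries. A positive value within a library thus forces negative ones between libraries on average, and that contrast is no separate support for the block. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and at least 2-fold. Per-library log2 ratios had 0.5 added to each count. Gene lists were tested with limma 3.58.1 (camera with a preset correlation of 0.01 and with an estimated one, and fry). With an estimated correlation camera takes its p-value on the residual degrees of freedom, few with 6 allele columns and a library block. With a preset correlation it uses about the number of genes. A higher p with an estimated correlation thus does not by itself show correlation between genes. DESeq2 1.42.0 was an alternative. On simulated data with 200 changed genes among 9220, the test called 42%, 90%, 98% and 100% of genes changed 2-, 3-, 4- and 8-fold, and 1 of 9020 unchanged genes. The changed genes were drawn only from those averaging at least 20 counts per library, and the dispersion was that of the trend. These shares thus do not cover the weakest tested genes. The 3 libraries differed from each other by more than sampling noise. Peak overlaps were computed with numpy 2.4.6 and pandas 2.3.3 (Python 3.11.15) and Fisher and binomial tests with scipy 1.17.1. The overlap code recovered 300 of 300 planted overlaps. The overlap background moved peaks around each chromosome 20 times. Windows took gene spans and 5 kb either side, with 10 kb for H19, 20 kb for Meg3 and Zdbf2 and 40 kb for Rasgrf1. The plan had named windows around transcript starts, but the gene table holds neither transcripts nor strand, so spans were used. Of 22 anchors 21 were in the table, Nespas being absent from it. A one-allele window or gene had a shared peak on one allele and no shared peak on the other. The plan had been stricter and asked for no peak of the other allele in either sample. Random gene sets, 10000 in number, matched each anchor's span within 25%.

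Gene lists (maternally and paternally expressed, noncanonical imprinted, Kcnq1ot1 and Airn domains, X escape, trophoblast stem cell, trophoblast differentiation, fibroblast, primitive endoderm, pluripotency and H3K9me3 machinery genes) and the rule for named genes were fixed before the data were examined. The rule names the imprinted genes with the largest ratios, Xist and the called escape genes, mitochondrial genes, Nnt and Y-linked genes, and up to 10 autosomal genes per direction with the largest ratio among called genes outside the imprinted lists with at least 50 counts per library, the same direction in all libraries and a named symbol. It further names the marker genes with the most counts and each control region with a one-allele peak. X-linked genes other than Xist and the escape list, flanking and uncalled genes of the domains, and peaks in windows marked on both alleles were chosen after their values were seen. Alternatives were DESeq2, no scaling, other count filters, no block, each library left out, other minimum folds, autosomal genes only, stricter peaks, other windows and overlaps. Leaving out mitochondrial genes, and the peak association on autosomal genes only, were added after the data were seen.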

Results

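Trophoblast stem cells are the cultured stem cells of the placental lineage. The line studied here, C/B 6.2, came from a cross between the mouse strains CAST/EiJ and C57BL/6J, so that reads over strain differences could be assigned to the CAST or the C57 copy of a gene. The stated purpose was to follow the epigenetic state of imprinted loci, the genes that are expressed from only the maternal or only the paternal copy. The label of the line writes the CAST strain first, which by convention names the mother. The labels do not say outright which strain was the mother. Allelic gene counts were deposited for 3 RNA libraries, and H3K9me3, a histone mark of silent chromatin, was mapped by CUT&RUN in 2 samples with a peak list for each allele. A sample with an IgG control antibody completed the 6 samples. The libraries held 1981167, 1044264 and 1552265 allelic counts over 55487 genes. Nothing in the labels says that the libraries came from separate cultures, so that the p-values below measure only the spread between these libraries, which may be technical.

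On the autosomes more RNA counts were assigned to C57 than to CAST. RNA of other cells of C57 origin, weighed further below, would be counted as C57 too. A C57 lean is therefore not by itself a difference between the copies within the line. Over 8916 tested autosomal genes the median log2 ratio of C57 to CAST counts was 0.58 ± 0.04 (SD, n = 3 libraries), a C57 share of 59.8% at the median gene. The shift was not the same on all chromosomes. Chromosome 11 lay at a median log2 ratio of 1.08 over 776 genes and chromosome 10 at 0.80 over 474 genes, while chromosomes 4 and 17 had the lowest autosomal medians, both at 0.41. The other medians ran from 0.47 on chromosome 1 to 0.62 on chromosome 6. The per-gene tests that follow took out the overall shift by TMM scaling, after which the median autosomal log2 ratio was 0.02. Where a C57 share is given, it is the unscaled share of counts, for single genes as mean ± SD of the 3 libraries. Median shares of gene sets, and counts of genes by share, use counts pooled over the libraries unless stated otherwise.

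**Figure D1:**
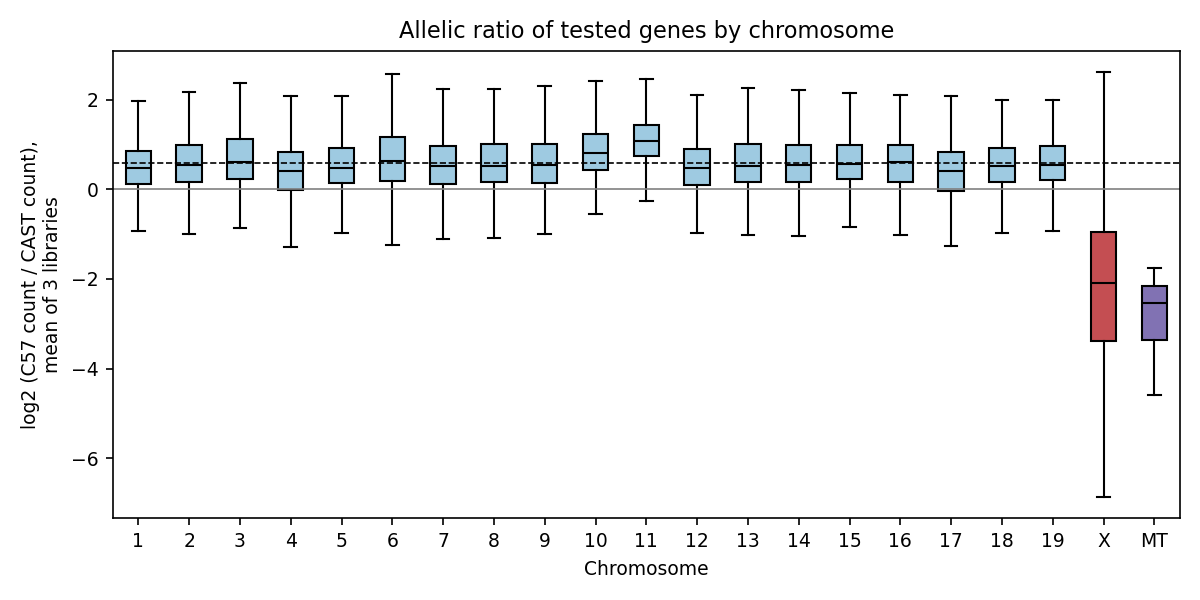
Unscaled log2 ratio of C57 to CAST counts (vertical axis, mean of 3 libraries per gene) by chromosome (horizontal axis), for 9165 tested genes placed on a chromosome. Boxes span the quartiles with the median as a line, whiskers reach 1.5 times the box height, outliers are not drawn, the dashed line is the autosomal median of 0.58 and the solid line marks equal counts. Chromosome 11 lies above the other autosomes, and the X and the mitochondrial genes (MT) lie far below, at medians of -2.09 and -2.54.

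The first comparison asked which expressed genes differed between the alleles. Of 9220 genes tested, 1531 differed at least 2-fold, 941 with more C57 and 590 with more CAST counts. The genes named next had the largest ratios among called autosomal genes outside the imprinted lists with at least 50 counts per library. On the C57 side, Sema3c, a secreted guidance factor, had 819 C57 counts and no CAST count, which allows a CAST share of up to 0.366%. Serpinf1, a secreted inhibitor of blood vessel growth, had 629 against 0, the caveolar protein gene Cav1 516 against 0, the collagen gene Col8a1 515 against 0, the gap junction gene Gja1 468 against 0, and Lox, which crosslinks collagen, 467 against 0. Dkk2, Aqp1 and Sema3a also had no CAST count, with 452, 281 and 276 C57 counts. Vim, the intermediate filament gene of mesenchymal cells, had 20831 C57 and 23 CAST counts, a C57 share of 99.9% ± 0.0348. On the CAST side each of the genes named by this rule had C57 counts, whereas of all 8916 autosomal genes, imprinted and weakly expressed ones included, 28 had a C57 share under 10% and 380 one over 90%. The C57 share was 4.28% ± 0.324 for the polarity kinase gene Prkcz, 15.5% ± 4.39 for the copper transporter gene Atp7b, 18.2% ± 4.61 for Phf11d, 17.7% ± 4.84 for Satb1, a chromatin organiser gene, and 19.1% ± 3.19 for Psd3. It was 18.8% ± 6.64 for Arhgef16, 22.0% ± 3.96 for the coagulation inhibitor gene Tfpi, 22.5% ± 3.23 for Casz1 and 22.7% ± 1.66 for Prom1. Prkcz and Arhgef16 lie in the last 10 Mb bin of chromosome 4, which leaned to CAST as a region, as described further below. Rps6 also leaned to CAST, with a C57 share of 12.5% ± 1.79, but ribosomal protein genes have many near-identical pseudogenes that can take or give reads. Each of these genes passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with adjusted p from 3.77e-14 for Prom1, the weakest, to 1.85e-116 for Sema3c, apart from Vim, whose p was too small to be written as a number above 0. DESeq2 in place of edgeR called 1018 genes. Without scaling between the alleles the count was 2499, of which 87.5% were higher on C57 against 61.5% with scaling.

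Marker lists of cell types were compared with other genes one at a time and not with each other. Of the 16 tested trophoblast stem cell genes, 14 were not called, and the median C57 share was 50.4%. The keratin gene Krt8 had 5757 C57 and 5661 CAST counts, Krt18 3423 and 3286, and the transcription factor genes Eomes 594 and 601 and Tfap2c 990 and 977. The median unscaled log2 ratio of the list was 0.02, equal counts, and -0.54 after scaling, so that its direction depends on the scaling: the list lay below the autosomal genes as a whole (camera, adjusted p = 2.84e-06; adjusted p = 0.0904 with an estimated correlation). Satb1 and Sox21, at C57 shares of 17.7% ± 4.84 and 35.0% ± 8.98, were its called members, both higher on CAST. Of 8 tested fibroblast genes, 6 were higher on C57 and none on CAST, with a median C57 share of 94.4% (camera, adjusted p = 2.51e-09; adjusted p = 0.0904 with an estimated correlation). The type I collagen genes Col1a1 and Col1a2 had C57 shares of 99.6% ± 0.147 and 99.7% ± 0.15, and the mesenchymal transcription factor gene Prrx1 had 136 C57 counts and no CAST count, a limit of 2.21% for CAST. Col3a1, at 70.9% ± 3.08, and Postn, at 75.4% ± 7.68, were not called; without scaling Col3a1 was (log2 ratio 1.32; edgeR, adjusted p = 0.000312). Of 6 tested genes of trophoblast differentiation, with a median log2 ratio of 0.44 before and -0.14 after scaling, 1 was called, Syna, a placental fusion gene, with a C57 share of 41% ± 1.72. Among 4 primitive endoderm genes, Pdgfra (90.2% ± 1.54) and Dab2 (98.5% ± 1.35) were higher on C57 and the laminin gene Lama1 (24.8% ± 4.22) on CAST. Of 3 pluripotency genes, Zfp42 was higher on CAST at 42.1% ± 1.77 C57. The calls of Sox21, Syna and Zfp42 rest on the scaling, since without it their log2 ratios were -0.86, -0.53 and -0.45, under 2-fold. The lists of trophoblast differentiation, primitive endoderm and pluripotency did not pass the threshold by camera, with adjusted p = 0.385, 0.433 and 0.077.

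**Figure D2:**
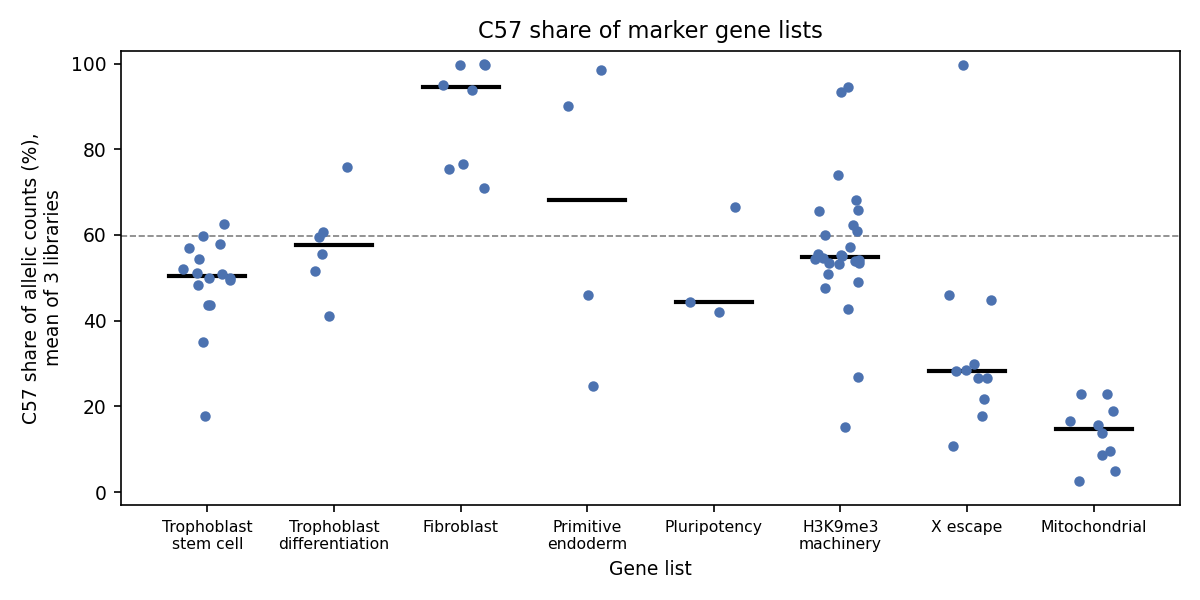
C57 share of allelic counts (vertical axis, %) for the tested members of 8 gene lists (horizontal axis). Each point is a gene, as the mean of 3 libraries. The thick line is the median of these means in the list and the dashed line their autosomal median (59.8% by pooled counts). Trophoblast stem cell genes gather around 50%, fibroblast genes lie above 70%, and the mitochondrial genes lie below 25%.

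Genes known as maternally expressed asked whether the imprint was read from the CAST copy. Of 32 listed genes 20 were tested: 9 were higher on CAST, 2 on C57 and 9 were not called. Adjusted over the list alone, the counts were again 9 and 2. The growth-restraining genes of the Kcnq1ot1 domain were close to monoallelic. Cdkn1c, a cell cycle inhibitor gene, had 984 CAST and 5 C57 counts, a C57 share of 0.414% ± 0.401 (edgeR, adjusted p = 1.69e-211), and Phlda2, a restraint on placental growth, had 634 and 2, a pooled C57 share of 0.314% with a 95% Clopper-Pearson interval of 0.0381% to 1.13% (edgeR, adjusted p = 7.78e-150). Ascl2, needed for the spongiotrophoblast, had 26 CAST and 4 C57 counts, and it had too few counts to be tested without library 1 or without library 3. In the Dlk1-Meg3 domain the long noncoding RNAs Meg3 (2.24% ± 2.02 C57), Rian (1.32% ± 1.14) and Mirg (78 CAST counts and no C57 count, a limit of 3.85%) were CAST-derived. Igf2r, the growth factor receptor opposite Airn, had a C57 share of 8.6% ± 2.54, Zim1 2.78% ± 4.81 and Gnas 27.5% ± 7.47. H19, a maternally expressed noncoding RNA, had a C57 share of 44.2% ± 3.65, with a log2 ratio of -0.93 after scaling (edgeR, adjusted p = 7.81e-05) and -0.37 without it (edgeR, adjusted p = 0.141), and Grb10 stood at 55.2% ± 1.86, with a log2 ratio of -0.26 after scaling and 0.3 before it. Neither reached a 2-fold difference. Pon3, with 49 C57 counts and no CAST count, and Pon2, at 92.0% ± 1.45 C57, were higher on the other copy; both lie next to Peg10, and the fibroblast list showed the same C57 lean. The list as a whole leaned to CAST (camera, adjusted p = 8.89e-09; adjusted p = 0.0808 with an estimated correlation), although its median C57 share, 43.3%, comes from members that went both ways.

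Genes known as paternally expressed leaned to the C57 copy, with exceptions. Of 37 listed genes 18 were tested: 14 were higher on C57, 1 on CAST and 3 were not called, and the counts were 14 and 1 adjusted over the list alone. Peg10, a retrotransposon-derived gene needed for the placenta, had 16190 C57 and 6 CAST counts, a C57 share of 99.96% ± 0.0179, and the zinc finger gene Peg3 had 7745 and 7 (99.9% ± 0.0674). Kcnq1ot1, the antisense RNA that silences the Cdkn1c domain, had 761 C57 and 2 CAST counts, a pooled C57 share of 99.7% with a 95% Clopper-Pearson interval of 99.06% to 99.97% (edgeR, adjusted p = 1.39e-98). The amino acid transporter gene Slc38a4 stood at 99.6% ± 0.352 (edgeR, adjusted p = 3.51e-143). Plagl1, Zrsr1 and Mest had 124, 92 and 47 C57 counts and no CAST count, which allows CAST shares of up to 2.42%, 3.26% and 6.38%. Airn, the antisense RNA of the Igf2r domain, stood at 88.6% ± 7.6 (edgeR, adjusted p = 0.00148; DESeq2, adjusted p = 0.0515). It overlaps Igf2r on the opposite strand, and the files do not say whether reads were counted by strand. Impact, at 75.5% ± 6.95, was the weakest call (edgeR, adjusted p = 0.029); without library 2 its adjusted p was 0.205 and without library 3 it was 0.117. The uncalled genes were Jade1, Smoc1 and Platr4, the last with 17 C57 and 18 CAST counts. Jade1 was called without scaling (log2 ratio 1.23; edgeR, adjusted p = 4.65e-07) and without library 1 (1.05; edgeR, adjusted p = 0.00815). Dlk1, a growth regulator gene, went the other way, with 80 CAST and 3 C57 counts, a pooled C57 share of 3.61% with an interval of 0.752% to 10.2% (edgeR, adjusted p = 1.52e-13). By camera the list leaned to C57 (adjusted p = 6.28e-14; adjusted p = 0.0808 with an estimated correlation). C57 shares near 100% were also those of the fibroblast list, so that a high C57 share was not particular to this list.

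**Figure D3:**
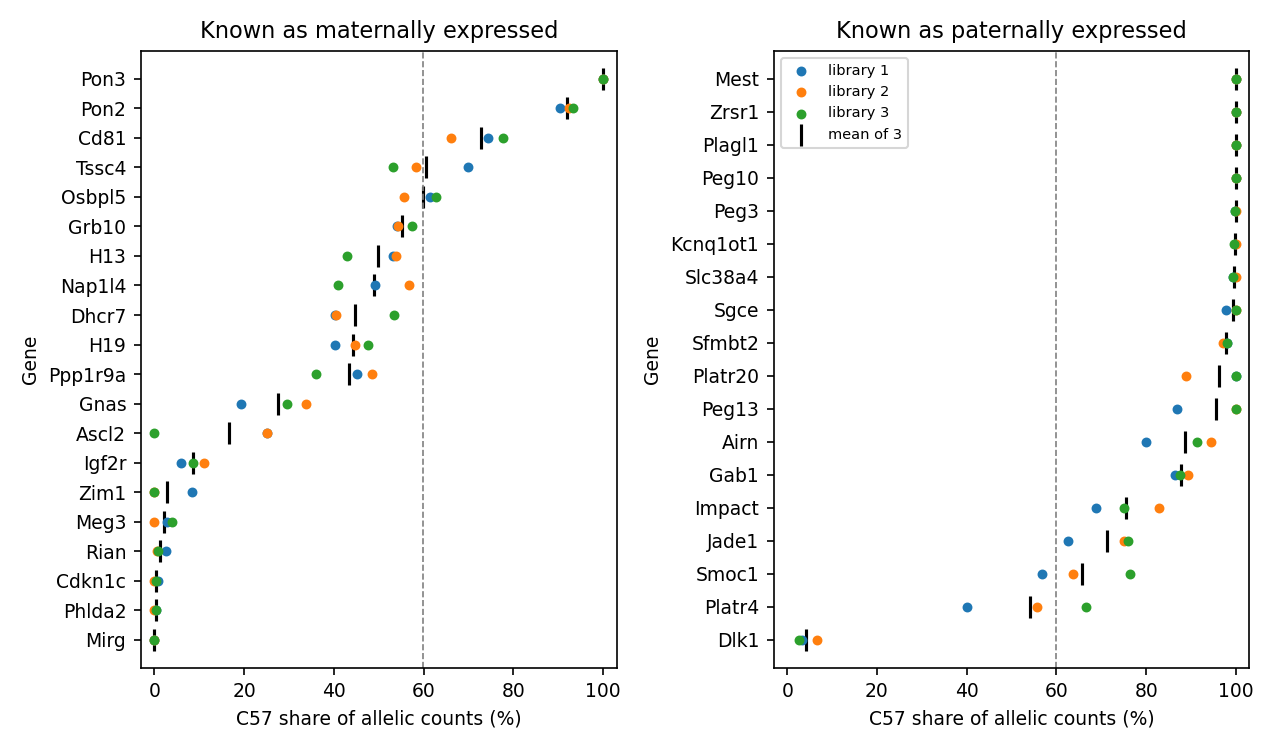
C57 share of allelic counts (horizontal axis, %) of the tested genes known as maternally expressed (left, 20 genes) and paternally expressed (right, 18 genes). Points are the 3 libraries, black ticks their mean, and the dashed line the autosomal median of such means (59.8% by pooled counts). Cdkn1c, Phlda2 and Mirg lie near 0%, Peg3, Peg10 and Kcnq1ot1 near 100%, and Dlk1 lies at 4.2% among the paternally expressed genes.

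Smaller imprinted groups were tested separately and not against each other. The 7 genes of noncanonical imprinting, which in mice rests on histone marks and is kept mainly in placental tissue, were all tested: 4 were higher on C57 and 3 were not called (camera, adjusted p = 3.46e-07; adjusted p = 0.0904 with an estimated correlation). Sfmbt2 stood at 97.7% ± 0.517 C57 and Gab1 at 87.8% ± 1.44 (edgeR, adjusted p = 3.15e-81), Slc38a4 and Platr20 were the other called members, and Jade1 and Smoc1 had 71.2% ± 7.43 and 65.6% ± 10 without a call. In the Kcnq1ot1 domain 3 of 11 tested genes were higher on CAST and none on C57 (camera, adjusted p = 0.0137; adjusted p = 0.176 with an estimated correlation). They were Cdkn1c, Phlda2 and Ascl2, while flanking genes such as Nap1l4 (49.0% ± 7.92) and Osbpl5 (60.0% ± 3.71) were not called. With DESeq2 Ascl2 lost its call (adjusted p = 0.0692). Cd81 of this domain was called higher on C57 without scaling (log2 ratio 1.43, edgeR, adjusted p = 2.37e-07). It was also called without library 2 (1.09, edgeR, adjusted p = 0.00773). In the Airn domain 3 of 11 were higher on CAST and none on C57 (camera, adjusted p = 0.00216; adjusted p = 0.138 with an estimated correlation). They were Igf2r, Mrpl18 (39.0% ± 9.29) and Acat2 (34.8% ± 21.2), and the last varied widely between libraries, with an adjusted p by edgeR of 0.16 without library 1 and 0.137 without library 2, and of 0.106 by DESeq2. Without scaling only Igf2r of these 3 passed the threshold, with edgeR adjusted p = 0.0651 for Mrpl18 and 0.0981 for Acat2.

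X-linked genes were expressed mainly from the CAST X. Of 239 tested genes 191 were higher on CAST, 20 on C57 and 28 were not called. Adjusted over the list alone, 193 were higher on CAST and 20 on C57. For every other list the counts adjusted over the list alone were the same as those given. With an estimated correlation no list passed an adjusted p of 0.05, but that form of the test has few degrees of freedom. For the X-linked list the estimated correlation was 0.0177, beside the preset 0.01. By fry, the unadjusted p was 2.69e-04 for the X-linked list. It was 3.07e-04 for the maternally and 7.91e-04 for the paternally expressed list. The highest fry p of the lists was 0.212, for trophoblast differentiation. The median unscaled log2 ratio was -2.01 ± 0.04 on the X against 0.58 ± 0.04 on the autosomes (SD, n = 3 libraries), a difference of -2.59 ± 0.05 that was below 0 in each of the 3 libraries (camera, adjusted p = 5.91e-47; adjusted p = 0.0758 with an estimated correlation). Esx1, a homeobox gene of the placenta, had 861 CAST counts and no C57 count, a limit of 0.348%. Wnk3 and Nexmif had 337 and 282 CAST counts and no C57 count, and Nrk, Hdac6 and Dusp9 had C57 shares of 0.869% ± 0.337, 1.04% ± 0.321 and 0.66% ± 0.579. Xist, the noncoding RNA that coats and silences an X chromosome, came from the C57 copy, with 3897 C57 and 13 CAST counts (99.7% ± 0.111). Tsix, its antisense partner, had 46 and 3, an excess past the threshold with edgeR (adjusted p = 0.00279) but not with DESeq2 (adjusted p = 0.141). Its C57 counts were 36, 2 and 8 in libraries 1, 2 and 3. The files do not say whether reads were counted by strand, so Xist reads may be among those counts. Of 11 tested genes listed as escaping silencing, 8 were higher on CAST and 1, Xist, on C57, with C57 shares of 26.6% ± 3.7 for Kdm5c, 28.3% ± 0.985 for Eif2s3x and 10.7% ± 3.88 for Ddx3x. Jpx and Car5b were not called. The C57-biased X-linked genes included the extracellular matrix genes Bgn, with 1228 C57 counts and no CAST count, and Timp1, with 135 and none, and the cytoskeletal genes Msn (82.0% ± 3.26), Flna (75.7% ± 1.49) and Pls3 (90.7% ± 2.1). Of the X-linked genes, 22 had a pooled C57 share under 1%, 23 between 1% and 5%, 20 between 5% and 10%, 55 between 10% and 20%, 82 between 20% and 50%, and 37 of 50% or more.

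Mitochondrial transcripts gave a second view of the maternal strain, since mitochondria pass through the mother. All 10 tested mitochondrially encoded genes were higher on CAST, with a median C57 share of 14.5% (camera, adjusted p = 6.91e-68; adjusted p = 0.0758 with an estimated correlation). The C57 share was 9.61% ± 1.62 for mt-Co1 and 22.9% ± 1.4 for mt-Cytb. Copies of mitochondrial sequence in the nuclear genome, or RNA of other cells of C57 origin, can add C57 reads. Mitochondrial genes took 16.5%, 16.9% and 12.1% of the counts of the 3 libraries, nearly all of it ribosomal RNA. No count fell on a Y-linked gene, and Nnt, which the C57BL/6J strain lacks in part, was not tested for want of counts.

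H3K9me3 peaks were about as many on both alleles. The authors' lists, called per sample and allele, held 24200 C57 and 21877 CAST peaks in sample 1 and 23838 and 22026 in sample 2, covering 15.8, 14.1, 15.3 and 14.1 Mb of the autosomes. The antibody labels of the samples differ, ab8898 and ab8899. Of the sample 1 peaks, 21.8% on C57 and 22.7% on CAST overlapped a peak of the same allele in sample 2 by at least 1 bp, against 1.22% and 1.10% after moving the peaks along the chromosome. Between alleles the overlap was lower, 14.0% in sample 1 and 11.5% in sample 2. Of 5266 autosomal C57 peaks found in both samples, 3162 (60.0%) had no CAST peak in either sample, and 2782 of 4960 CAST peaks (56.1%) had no C57 peak. Most sample 1 peaks also lacked a peak of the same allele in sample 2. A missing peak on the other allele can thus be a peak that was not detected, and these shares do not measure allele-specific marking. The peaks were weak, with a lowest authors' score of 10, which stands for a q value of 0.1, and medians of 13 to 14. With 2 samples against 2, no exact two-sided permutation test can go below p = 0.33, and no other test was run on these counts. Shared peaks divided unevenly over chromosomes: 636 on C57 against 179 on CAST on chromosome 11, 209 against 638 on chromosome 1, and 238 against 482 on chromosome 4. Over all peaks of samples 1 and 2 the division was less uneven. Chromosome 11 had 1883 C57 against 876 CAST peaks and 1797 against 914. Chromosome 1 had 1501 against 2315 and 1466 against 2437, and chromosome 4 had 1371 against 1579 and 1248 against 1469. On the X, 51 C57 and 166 CAST peaks were shared, against 5266 and 4960 on the autosomes (Fisher's exact test over peaks, two-sided, p = 9.66e-17). Peaks are not independent of their neighbours, so that this p overstates the evidence.

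**Figure D4:**
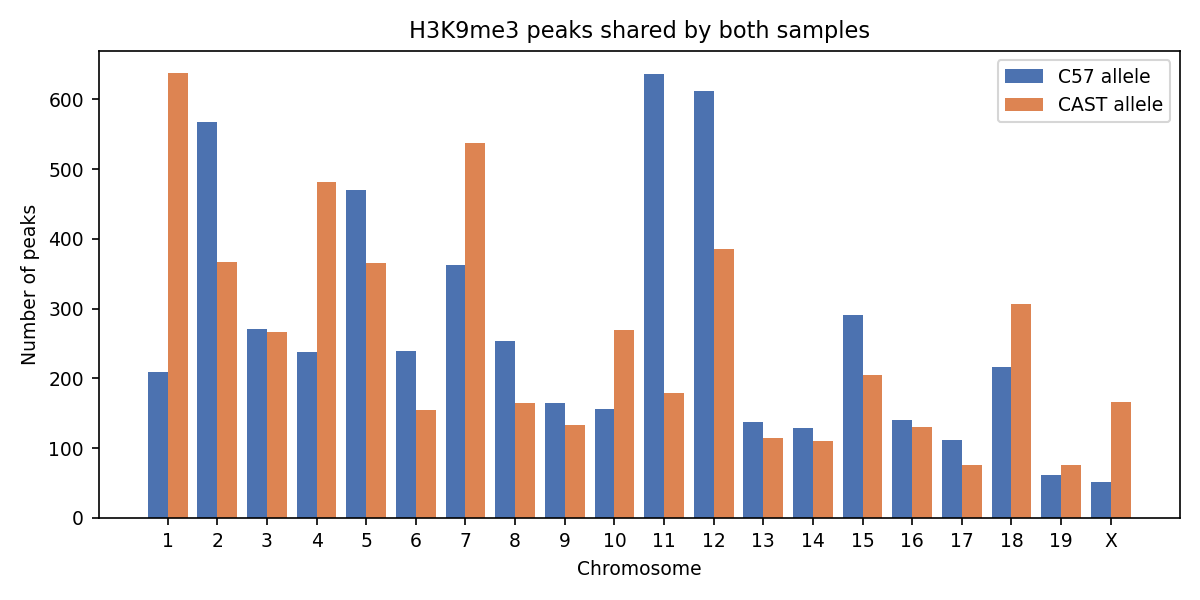
Number of H3K9me3 peaks (vertical axis) found in both samples on the C57 and the CAST allele, by chromosome (horizontal axis). By ratio, C57 peaks exceed CAST peaks most on chromosome 11 (636 against 179), and CAST peaks exceed C57 peaks most on chromosome 1 (209 against 638) and the X (51 against 166).

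At imprinted control regions, the elements whose DNA methylation from one parent sets the imprint, H3K9me3 peaks were compared between the alleles, taking CAST as the mother. Coordinates are those of the authors' shared lists, whose build is inferred as GRCm38 and not stated. Of 17 windows around genes with maternal methylation, 4 had a shared peak on CAST alone (Peg3, Mest, Nap1l5 and Zrsr1), 1 on C57 alone (Inpp5f), 3 on both and 9 on neither (CAST alone against C57 alone, exact binomial test, two-sided, p = 0.375). With so few one-allele windows, that binomial test could not reach a p under 0.05 even if all lay on the same allele. It therefore cannot decide for or against a lean to CAST in these windows. Random sets of 17 genes with spans of similar length had 0.328 CAST-only windows on average, and 1 of 10000 sets reached 4 (permutation p = 2e-04), a test of whether such windows carry CAST-only peaks more often than other genes and not of CAST against C57. Of 4 windows with paternal methylation, H19 and Meg3 had C57 peaks alone, Rasgrf1 had both and Zdbf2 none. Over all one-allele windows, 6 of 7 lay on the methylated parent's allele (exact binomial test, two-sided, p = 0.125). Single peaks in the maternal windows were also held to the planned rule of no peak of the other allele there in either sample. By that rule 5 anchors had a CAST peak and 2 had C57 peaks. Both of the latter, Kcnq1ot1 and Airn, were also among the 5. The Peg3 peak spanned chromosome 7 from 6728009 to 6729548 within the gene, with an authors' fold enrichment of 3.33. The Nap1l5 peak lay on chromosome 6 from 58906415 to 58908060, where Nap1l5 sits inside Herc3, the Zrsr1 peak on chromosome 11 from 22972187 to 22972751, where Zrsr1 sits inside Commd1, and the Mest peak on chromosome 6 from 30737010 to 30737298. A C57 peak overlapped the Mest peak in 1 sample. The Inpp5f peak, on C57, ran from 128687589 to 128688175 on chromosome 7, and a CAST peak overlapped it in 1 sample. In the Kcnq1ot1 and Airn windows the alleles carried peaks at different places. These windows take in the whole gene spans, 93.4 and 128.6 kb with the extension. Their class of peaks on both alleles thus does not mean that both alleles were marked at the control region itself. A CAST peak lay on chromosome 7 from 143295312 to 143296139, in Kcnq1ot1, and C57 peaks from 143235883 to 143236776 and from 143238286 to 143239264. In the Airn window the CAST peak, on chromosome 17 from 12742202 to 12742885, lay where Airn and Igf2r overlap, and the C57 peak lay from 12827139 to 12827954 in Airn. The Impact peaks of both alleles overlapped. On the paternal side, a C57 peak lay beside H19 on chromosome 7 from 142580579 to 142583073, where a CAST peak was called in 1 sample. The Meg3 window held 8 C57 peaks and no CAST peak. The strongest of those 8 by the authors' score, from 109527207 to 109531277 on chromosome 12, lay outside the Meg3 span, over the predicted gene Gm34081. Of 1978 stretches of the same 70.7 kb within 5 Mb, 74 held as many C57 peaks with no CAST peak (permutation p = 0.038).

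Whether H3K9me3 of one allele went with expression of the other was asked over all tested genes. Among genes higher on C57, 20 had a shared peak on C57 alone and 23 on CAST alone within the gene or 5 kb of it. Among genes higher on CAST, 9 had one on C57 alone and 5 on CAST alone. For genes higher on C57 the counts may include RNA of other cells of C57 origin. Such counts need not show which copy the line reads. The odds ratio was 0.483 (Fisher's exact test over genes, two-sided, p = 0.358), so that no association was detected. With that limit and this number of genes, none is excluded either. By Fisher's exact test it was 0.137 (p = 0.0934) with a 4-fold minimum for expression and 1.33 (p = 1) with only peaks of at least the median score. Of single genes, Peg3, Mest and Zrsr1 were read from C57 and marked on CAST, and Meg3 and Dlk1 were read from CAST and had marked C57 neighbourhoods. Igf2r was read from CAST and had its peak on CAST, in the stretch shared with Airn. These genes were chosen after their values were seen.

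H3K9me3 over gene classes set gene families against other protein-coding genes. Zinc finger (Zfp) genes, a textbook site of the mark, carried a shared peak in 6 of 397 genes on C57 (1.51%) and in 5 on CAST (1.26%), against 1.94% and 1.88% of 19599 other genes (Fisher's exact test, two-sided, adjusted p = 0.791 and 0.57). Protocadherin genes carried C57 peaks in 16 of 69 (23.2%; adjusted p = 4.06e-12) and a CAST peak in 1 (adjusted p = 1). Apart from Pcdh15, the C57-marked members were neighbouring genes, 13 of the alpha and 2 of the beta group, whose gene spans overlap, so that they are not independent. By distinct peaks the class held 17 on C57 and 23 on CAST, the latter all over Pcdh15. The gene counts thus do not mean that the class had fewer CAST peaks. Olfactory receptor genes carried peaks less often, in 0 of 1110 on C57 and 4 on CAST (adjusted p = 5.88e-09 and 7.11e-05). Their median span of 0.95 kb, against 19.5 kb for other genes, offers less room for a peak. Vomeronasal receptor genes carried a peak in 3 of 355 on either allele (adjusted p = 0.384 for both), and none of 97 ribosomal protein genes carried one (adjusted p = 0.384 for both).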

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

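The run without mitochondrial genes and the peak association on autosomal genes were chosen after the results were seen. The count of 1531 called genes (941 higher on C57, 590 on CAST) became 1018 (627 and 391) with DESeq2, 684 (408 and 276) with at least 50 counts per library, 2499 (2187 and 312) without scaling, 2796 (1486 and 1310) with no minimum fold and 784 (522 and 262) at 4-fold. Scaling and thresholds set these changes by construction; the cause of the DESeq2 difference was not tested. Of the DESeq2 calls, 1014 were among the 1531. Leaving out a library gave 1342 to 1374 genes, and without the replicate block 1487, with 9 maternally and 14 paternally expressed genes called in the known direction, as with the block. Leaving out mitochondrial genes gave 1527. By camera the maternally and paternally expressed lists kept their direction with DESeq2, without scaling, under other count filters, without the block, with a library left out and without mitochondrial genes; the smaller imprinted lists were not rerun. The paternally expressed list fell from 14 to 6 C57 calls with at least 50 counts, where fewer genes were tested. The X minus autosome difference of -2.67 in the fit was -2.13 with no count filter, -2.99 at 50 counts, -2.6 without the block, and -2.61 to -2.54 with a library left out; the cause was not tested. Grb10, not called, turned from -0.26 to 0.304 and Platr4 from -0.51 to 0.0349 without scaling. Without scaling the uncalled Krt8, Krt18, Tfap2c, Trim28 and Setdb1 turned from below 0 to 0.045, 0.0606, 0.00314, 0.33 and 0.315. Uncalled Tssc4 and Osbpl5 turned to -0.264 and -0.0353 without library 1. Without library 2 Osbpl5 stood at 0.151, and without library 3 Osbpl5 turned to -0.0233 and Tssc4 stood at 0.400. Of 102 genes followed, 14 lost an adjusted p under 0.05 with DESeq2 and 88 kept theirs on the same side of it. Called genes among the 14 were Airn (0.0515), Ascl2 (0.0692), Zfp57 (0.0692), Acat2 (0.106), Tsix (0.141) and Impact (0.24). Without scaling Acat2, Agrn, Mrpl18, Sox21, Syna and Zfp42 lost their calls and Cd81, Col3a1 and Jade1 gained one. With a library left out, calls were lost by Acat2, Suv39h1 and Zfp42 (library 1), Acat2, Impact, Mrpl18, Suv39h1 and Zfp42 (library 2) and Impact (library 3), and gained by Ppp1r9a and Jade1, Ppp1r9a and Cd81, and H19 and Dhcr7. Zfp42 also lost its call under both other count filters. C57-only and CAST-only peaks fell from 3162 and 2782 to 1082 and 984 with overlap of at least 50% of each peak, and to 1634 and 1615 with scores at or above the median. Single samples gave 20805 to 21101 and 18454 to 19325, since no second sample was required. C57-only maternal windows went from 1 to 2 with stricter scores. The odds ratio of peaks and expression went from 0.483 to 1.33 with stricter scores and to 0.137 (Fisher's exact test, p = 0.0934) with a 4-fold minimum for expression, none past the threshold. Zfp genes with a CAST peak went from 1.26% to 2.77%, vomeronasal genes from 0.845% to 2.54% with 5 kb added, and protocadherin genes stood at 1.45% on CAST under both score limits, with the direction against other genes reversed. Leaving out a sample for windows and genes, and windows at transcript starts, were not run, since the lists that could be placed on genes join both samples and the gene table has no transcripts. Depth was not varied. Of 50 simulated 2-fold differences 31 passed the adjusted p and 21 also the fold minimum. Depth sets the limits on counts of 0, such as 6.38% for Mest with 47 counts.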

Other observations

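Genes of the H3K9me3 machinery were mostly read from both alleles. Of 26 tested, 22 were not called, among them Trim28 (C57 share 55.6% ± 2.53) and Setdb1 (55.2% ± 3.15), and the list, with a median log2 ratio of 0.28 before and -0.27 after scaling, did not pass the threshold (camera, adjusted p = 0.0611). Its 25 autosomal members had an unscaled median of 0.297, and 189 of 10000 matched random lists had so low a median, a test chosen after the values were seen. The exceptions included both zinc finger genes known to protect imprints. Zfp57 had 36 C57 and 2 CAST counts (edgeR, adjusted p = 0.00205; DESeq2, adjusted p = 0.0692), and Zfp445 stood at 26.8% ± 7.66 C57 (edgeR, adjusted p = 2.24e-18). Zfp445 also had a shared H3K9me3 peak on C57 alone. Atf7ip, a partner of the methyltransferase Setdb1, was higher on C57 at 93.3% ± 4.71, and the X-linked methyltransferase gene Suv39h1 had 5 C57 and 25 CAST counts, with an adjusted p of 0.00239 by edgeR that was 0.064 without library 1 and 0.123 without library 2.

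All tests in the weighing below were chosen after the results were seen. The libraries showed an autosomal C57 excess together with fibroblast genes of almost pure C57 origin. A uniform preference of mapping for the C57 reference would lift stem cell genes alike, but the upper quartile of the trophoblast stem cell list was a log2 ratio of 0.286, under the autosomal median of 0.58, and 4 of 10000 matched random lists had so low a median. The 6 trophoblast differentiation genes, with a median of 0.44 and an upper quartile of 0.626, at the 35.5th percentile, did not set themselves apart from other genes. RNA of admixed C57 cells, such as the fibroblasts on which such stem cells are often grown, is a candidate explanation: every tested fibroblast gene lay above the autosomal median, the lowest at 70.9% C57, with Vim at 20831 and Col1a1 at 2965 C57 counts, and Pdgfra of the endoderm list is also a fibroblast gene. The labels name no feeder cells. Higher expression of the C57 copy within the line stays open, because these counts do not part it from RNA of admixed C57 cells. That copy is the paternal one if CAST was the mother. Without a reverse cross among the samples, an effect of the parent could not be told from one of the strain.

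Chromosome 11 leaned further to C57 than other autosomes, and the last 10 Mb bin of chromosome 4 to CAST. The bin before it on chromosome 4 went partly the same way, at a median unscaled log2 ratio of 0.17. Of its 49 genes 17 were called higher on CAST and 1 on C57, and it had 7 shared C57 against 70 CAST peaks. A few strongly allelic genes would leave most genes in place, yet 83.2% of the 776 genes of chromosome 11 lay above the autosomal median, 86.9% of the 719 beyond its first 10 Mb but only 36.8% of the 57 within it, so that the lean did not reach that end. Admixed C57 cells alone would lift all chromosomes by similar amounts; chromosome 11 exceeded the other autosomal genes by 0.551 ± 0.028 as a whole and by 0.591 ± 0.0267 without that stretch (log2, SD of 3 libraries), against an SD of 0.0879 between the other chromosomes. Unequal copy numbers in the line are a candidate explanation, since the log2 ratio of shared C57 to CAST H3K9me3 peaks was 1.83 on chromosome 11, above the 0.66 maximum elsewhere, and -4.58 at the end of chromosome 4 (12 against 287 peaks), where the median unscaled log2 ratio of 58 genes was -0.75 and 33 were called higher on CAST after scaling, among them Prkcz and also Agrn, which without scaling was under 2-fold at -0.944. Over all peaks of samples 1 and 2 the log2 ratio on chromosome 11 was smaller, 1.10 and 0.98. The next highest autosome there, chromosome 12, had 0.51 and 0.52. Peak ratios can also part from RNA. Chromosome 10 had 156 shared C57 against 269 CAST peaks and an RNA median of 0.80. Chromosome 1 had 209 against 638 and 0.47. The first 10 Mb of chromosome 11 had 14 against 4 peaks and an RNA median of 0.42. Copy number was therefore not settled by these files.

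The C57 reads of X-linked genes may come from the same admixed cells. If the autosomal excess came from cells with a single active C57 X, the X-linked log2 ratio would be -2.02, and the observed value was -2.01, a mean difference of 0.014 ± 0.113 (SD, n = 3). By library the differences were 0.079, 0.079 and -0.117, so that opposite signs brought the mean near 0. The predicted values rose from -2.12 over -2.04 to -1.91, and the observed -2.04, -1.96 and -2.02 did not follow them. The C57 share of mitochondrial counts was 15.7% ± 1.5, beside an extra C57 part of 19.8% ± 1.17 of autosomal counts, and the relation of these values was not tested. Matrix genes such as Bgn and Timp1 were read from C57 alone, while Esx1 had no C57 count in 861. Escape from silencing on the C57 X cannot be told apart from this. The 8 listed escape genes outside the Xist region had a median C57 share, over their library means, of 27.5%. This was at the 89.3rd percentile of matched random X-linked lists.

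The 6 allele columns make 10 splits, too few for a share under 0.05. The real split called 1531 genes, only that 1 split reached the count, and the highest of the others was 0, the 3 others that part every library's alleles included. Every other split mixed C57 and CAST columns within a group, so that allele differences added to the spread within groups. Their counts of 0 therefore do not measure false calls. By the same test at an unadjusted p under 0.05, the real split had 3537 genes; the other splits were counted only at the adjusted threshold.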
